A study of Mus musculus with 34 samples.

How the data were processed

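The deposited values were log2 probeset signals, 1 column per array, which the authors had normalized between arrays before deposition. That they are log2 was read from the values themselves, which ran from 1.02 to 14.37 over all arrays together. Partek is named in the labels as the processing tool. Its version and role, and the methods of background correction, normalization and summarization, are not given in the sources used here. Per the labels, RNA was extracted with Trizol and biotinylated cRNA was hybridized to Affymetrix Mouse Gene 1.0 ST arrays. Lines, drugs, doses, days and viability (Trypan blue) come from the labels. The labels give lonafarnib in mM in the design text and in µM in the treatment protocol, and µM is printed here. Start and end cells came from a 10-cm dish and midpoint cells from a 15-cm dish or pooled 10-cm dishes, per the labels.

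Of 35557 probesets, 21789 were listed with one gene symbol and were used, 1621 were listed with several symbols and 12147 were not listed. For the 999 genes with more than one probeset the probeset with the highest mean over all 34 arrays was taken, which gave 19938 genes. In 57 genes other probesets were called in opposite directions in a comparison with the start. No symbol had to be updated, no column was left unassigned and no column pair was identical.

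Limma 3.58.1 in R 4.3.3 (with jsonlite 2.0.0) fitted a mean for each of 12 groups over 34 arrays with lmFit and eBayes, with 22 residual and 6.6986 prior degrees of freedom. Moderated two-sided p were adjusted by Benjamini-Hochberg over 19938 genes per comparison, and a gene was called at an adjusted p below 0.05. A further count took called genes that changed at least 2-fold. There were 12 comparisons over time, a comparison of start arrays in each line, and 8 differences of changes between drugs or lines. Arrays were not treated as paired.

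Fixed before the data were examined were 24 gene lists, written from general knowledge: fibroblasts, macrophages, granulocytes and mast cells, T and NK cells, pre-B identity, STAT5 targets, FOXO targets, mitosis, DNA replication, ribosome biogenesis, cholesterol synthesis, prenylation, p53 targets, the BCL2 family, the unfolded protein and integrated stress responses, interferon, MHC class II, lysosome and autophagy, glycolysis and hypoxia, oxidative phosphorylation, ABC transporters, NRF2 targets, adhesion and homing, and galectins. Limma's camera tested each with a preset correlation of 0.01 and again with an estimated correlation, adjusted over 288 tests over time and 192 of differences. Of the 288, 141 were called with the preset and 27 with the estimated correlation.

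Genes were named by a rule fixed before the data were examined. It took up to 5 rising and 5 falling genes of largest change per comparison with the start (3 each way elsewhere), called and with no overlap between the arrays of both groups. Left out were predicted genes, small RNAs and short symbols of capital letters and digits. Added were up to 3 members of a described list and 1 called the other way, 18 fixed genes, of which 14 were measured, and 8 each way among genes changed alike. H2-Ea outside this rule, Gata2, Xist and the Y-linked genes were chosen after values were seen.

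In a self-test with changes added to 200 genes, the Bin-2 comparison of 3 with 3 arrays recovered 52.2% of genes at 1.5-fold, 95.5% at 2-fold and 98.5% at 4-fold with 17 false calls. The 8093 comparison of 2 with 3 arrays recovered 37.3%, 95.5% and 100% with 9 false calls. In each the 1 shifted list was called and 0 other lists were. The simulated noise was independent between genes, so this does not test false list calls that arise when genes vary together. Each simulated gene also had the same spread in all 12 groups, as the SE of the fit takes it to have. In the data the spread of some genes differed. The SD of Lgals3 was 0.98 at the nilotinib end of Bin-2 and 0.06 at its start, a case the self-test does not cover. Relations across arrays used 100000 permutations. Raw array images and intensities were not used here.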

Results

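Gene expression was measured on 34 microarrays (Affymetrix Mouse Gene 1.0 ST) in a pair of mouse pre-B acute lymphoblastic leukaemia lines, 8093 and Bin-2. Both lines came from mice transgenic for BCR/ABL, the fusion kinase of Philadelphia chromosome-positive leukaemia. The 8093 leukaemia arose on an inbred C57BL/6J background and Bin-2 on a mixed one. The cells grew over irradiated embryonic fibroblasts, which serve as feeder cells, and only loosely attached or floating cells were collected. Each line was exposed continuously to nilotinib, an inhibitor of the ABL kinase, or to lonafarnib, an inhibitor of farnesyltransferase, the enzyme that attaches a farnesyl lipid to Ras and other proteins. Nilotinib was given at 20 nM to 8093 and 50 nM to Bin-2, and lonafarnib at 1 µM to 8093 and 0.25 µM to Bin-2. RNA was taken at the start (day 0), at a midpoint when few cells were viable, and at the end when viability had returned under drug. The midpoint was day 3 in all courses except 8093 with lonafarnib (day 4), and the end was day 20 (8093, nilotinib), 26 (8093, lonafarnib), 21 (Bin-2, nilotinib) or 30 (Bin-2, lonafarnib). Viability at the midpoint was 20% in 8093 with lonafarnib and 5 to 10% in the other courses, and about 90% at every end. RNA of viable and of dying cells cannot be told apart in these values, so changes at a midpoint may belong to either. The 12 groups held 3 arrays each, from separate plates, except the ends of both 8093 courses, which held 2. The number of arrays limits the precision. Values are log2 signals, and changes are given in log2 units ± the standard error (SE) of the fit over all 34 arrays. A gene was called at an adjusted p below 0.05 among 19938 genes. The interquartile range of an array's values averaged 3.03 at the nilotinib midpoint of 8093 and 3.16 at the lonafarnib midpoint of Bin-2, against 3.42 to 3.55 in the other groups.

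The start arrays of both drug courses of a line were compared first, since they had the same status before treatment. Lgals3, which encodes galectin-3, a sugar-binding protein, differed by 0.40 ± 0.35 between the starts of the 8093 courses (3 arrays each) and by -0.21 ± 0.35 between those of Bin-2. Limma called 0 genes in either line. At an unadjusted p below 0.05 there were 2350 genes in 8093 and 1085 in Bin-2. A limma fit with a trended, robust prior called 17 genes in 8093 and 0 in Bin-2. In 8093 a fit to the arrays of both its courses called 3 genes, a fit without dim genes 1 and the fibroblast covariate 2. Without replicate 1 of the nilotinib start the count in 8093 was 198. Among the gene lists, those of DNA replication (28 genes) and of oxidative phosphorylation (25) lay higher in the lonafarnib start of 8093 by means of 0.15 each, with camera adjusted p = 0.00183 and 0.00118. Neither held with an estimated correlation (adjusted p = 0.984 and 0.926 with an estimated correlation). In Bin-2 the fibroblast list lay higher in the lonafarnib start by a mean of 0.12 (adjusted p = 0.00183) and the interferon list lower by a mean of -0.11 (adjusted p = 0.0131). With an estimated correlation the adjusted p was 0.926 for each, and no single member of these 4 lists was called.

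**Figure D1:**
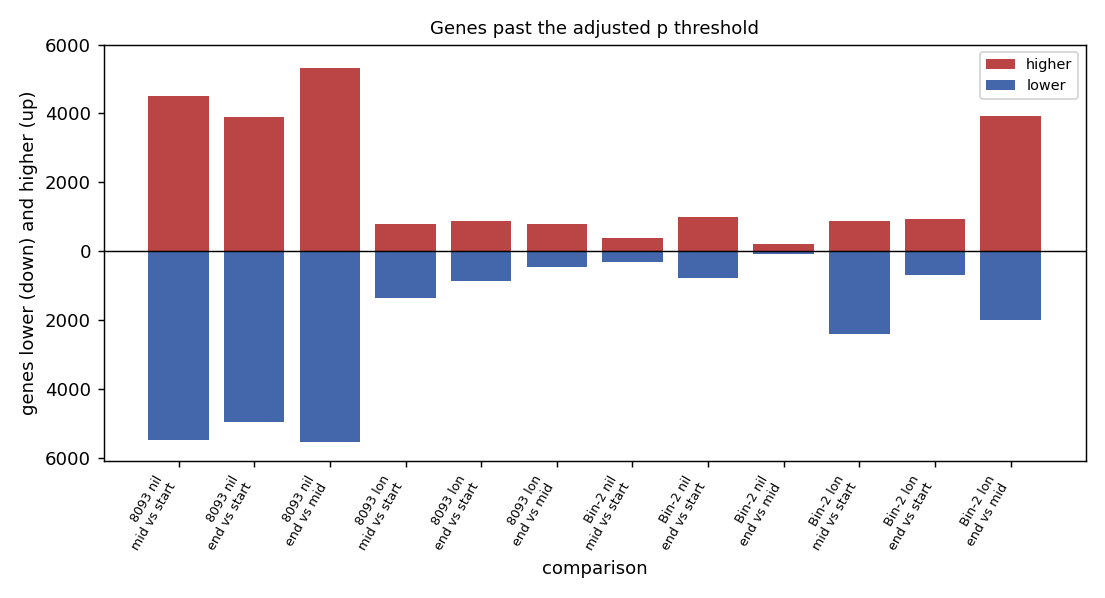
Genes called at an adjusted p below 0.05 in each comparison over time (horizontal axis), with the number higher drawn upwards and the number lower drawn downwards from 0 (vertical axis). The totals run from 282 genes (Bin-2 with nilotinib, end against midpoint) to 10871 (8093 with nilotinib, end against midpoint).

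Nilotinib in 8093 was followed to its midpoint to ask how the collected cells, of which 5 to 10% were viable, differed from the starting culture. Transcripts typical of mast cells and macrophages rose most in the 3 midpoint arrays over the 3 start arrays. Cpa3, the carboxypeptidase stored in mast cell granules, rose by 7.92 ± 0.26 (adjusted p = 3.28e-19), and Fcer1a, the ligand-binding chain of the high-affinity IgE receptor, by 6.85 ± 0.35. The mast cell proteases Mcpt1 (7.43 ± 0.45) and Mcpt2 (8.23 ± 0.53) and Lyz2, the lysozyme of macrophages (7.67 ± 0.53), rose as steeply. Start means of Fcer1a (3.23), Mcpt1 (2.93) and Mcpt2 (3.12) were no higher than the highest group mean of Y-linked genes (3.32), which were low in every group, so the size of these rises is not exact. Lgals3 went from 5.68 to 10.64, a rise of 4.96 ± 0.35 (adjusted p = 1.86e-12). Rasgrp3, an exchange factor that activates Ras in B cells, fell (-5.23 ± 0.27), as did Rnase12 (-4.02 ± 0.20) and Vat1l (-3.53 ± 0.19). Col1a1, the collagen chain made by fibroblasts, rose by 1.52 ± 0.13, Cish, a feedback inhibitor induced by STAT5, by 0.73 ± 0.14, and Bcl6, a transcriptional repressor of germinal centre and pre-B cells, by 0.80 ± 0.19. Myc (-0.23 ± 0.15, adjusted p = 0.207) and Il7r (-0.09 ± 0.16, adjusted p = 0.667) were not called. Limma called 9988 genes, of which 4503 rose and 5485 fell, and 2283 of these changed at least 2-fold. When every probeset was tested 15864 were called.

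Genes for growth and division fell together at this midpoint. The arrays were also more compressed here, with a mean interquartile range of 3.03 against 3.44 at the start. Bright lists are lowered by such compression and dim lists raised, so the size of falls of bright lists and of rises of dim lists is not exact. Start means were 9.41 for ribosome biogenesis and 9.76 for oxidative phosphorylation. Of the 26 measured mitosis genes 25 fell, also when adjusted over the list alone, among them the spindle checkpoint kinases Bub1 (-1.83) and Ttk (-1.81) and the anaphase activator Cdc20 (-1.61), with a camera adjusted p of 2.47e-16 that held with an estimated correlation. All 27 measured genes of ribosome biogenesis fell, also when adjusted over the list alone, by a median of -1.08, led by Rrp9 (-1.84) and Utp4 (-1.78), and this call held as well. All 28 genes of DNA replication fell, with the same 28 adjusted over the list alone. Gins1 (-2.29) and Rfc4 (-2.16), parts of the replication helicase and of the clamp loader, fell most (adjusted p = 4.06e-15; adjusted p = 0.085 with an estimated correlation). All 25 oxidative phosphorylation genes fell, 25 adjusted over the list alone, by a median of -0.99, Cyc1 by -1.57 (adjusted p = 5.99e-12; adjusted p = 0.108 with an estimated correlation). Of 20 cholesterol synthesis genes 13 fell, 13 adjusted over the list alone, Ebp by -1.06 and Hsd17b7 by -0.94 (adjusted p = 0.00796; adjusted p = 0.377 with an estimated correlation).

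Marker lists of macrophages, granulocytes and mast cells, and fibroblasts rose in the same arrays, while the T and NK cell list was not called (3 of 13 up and 3 down, the same numbers adjusted over the list alone; adjusted p = 0.642). Of 17 macrophage genes 15 rose, 15 adjusted over the list alone, with Itgam (4.86) and Msr1 (4.61) beside Lyz2 (adjusted p = 9.01e-11; adjusted p = 0.192 with an estimated correlation). Of 16 granulocyte and mast cell genes 9 rose, 10 adjusted over the list alone, and the call held with an estimated correlation. Fibroblast genes rose in 25 of 33 cases, 26 adjusted over the list alone, led by Thbs1 (4.98) and Fn1 (4.96), which macrophages also make (adjusted p = 2.72e-08; adjusted p = 0.0507 with an estimated correlation). The fibroblast list was dim at the start (mean 4.74), and compression raises dim lists, so the size of its rise is not exact. Of the 9 genes of MHC class II antigen presentation 8 rose and 1 did not pass, against 8 rising and 1 falling adjusted over the list alone. H2-Aa rose by 3.37, H2-Eb1 by 2.23 and the invariant chain Cd74 by 2.10 (adjusted p = 4.83e-05; adjusted p = 0.0877 with an estimated correlation). Of 26 lysosome and autophagy genes 15 rose and 3 fell, 15 and 3 adjusted over the list alone, with Cd63 at 4.51 and Ctsd at 3.00 (adjusted p = 1.55e-04; adjusted p = 0.374 with an estimated correlation). With the mean fibroblast signal of each array as a covariate limma called 3861 genes at this midpoint, and with the means of the macrophage and of the granulocyte and mast cell lists as covariates 759. These means differed between the groups compared, which costs precision. The fibroblast mean may also follow the compression of the arrays and not feeder RNA alone, which was not tested. The SE of the Lgals3 change went from 0.35 to 0.76 and 0.53 here. A lower count therefore does not show that RNA of such cells accounts for the changes, and this holds for all counts with covariates.

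By the end of the nilotinib course the 8093 cultures had lost most of the pre-B cell signal and had very high mast cell signal (2 arrays against 3). Of 31 pre-B cell genes 26 fell, 4 rose and 1 did not pass, 26 and 4 adjusted over the list alone, by a median of -2.19 (adjusted p = 8.05e-13, a call that held with an estimated correlation). Rag1, the recombinase of antigen receptor genes, fell (-4.68), as did Igll1 (-4.52) and Vpreb1 (-4.42), the surrogate light chain of the pre-B cell receptor. Btk, a kinase of B cells that mast cells also express, rose by 1.60. The mean of the list was 8.58 at the start, 8.52 at the midpoint and 6.46 at the end. In the same arrays Fcer1a rose by 9.61 ± 0.39, the receptor's beta chain Ms4a2 by 9.17 ± 0.36, Cpa3 by 8.89 ± 0.29 (adjusted p = 1.18e-20), F13a1, coagulation factor XIII A, by 8.68 ± 0.39 and the steroid-producing enzyme Cyp11a1 by 8.52 ± 0.28. With start means of 3.23 and 2.95, Fcer1a and Ms4a2 began at the level of the Y-linked genes, so the size of their rises is not exact. Rasgrp3 fell by 5.98 ± 0.30, Tmem119 by 5.35 ± 0.17 and Gria2, a glutamate receptor subunit, by 5.25 ± 0.32.

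Lgals3 stayed above the start at this end by 4.46 ± 0.39 (adjusted p = 4.62e-11). Cish rose by 2.21 ± 0.16 and Bcl6 by 1.57 ± 0.21. Bcl2l11, which encodes the death-promoting protein BIM, fell by 2.26 ± 0.14 (adjusted p = 2.27e-14), Il7r, the interleukin-7 receptor chain, by 2.23 ± 0.18, Socs2 by 2.17 ± 0.13 and Myc by 1.13 ± 0.17. Of 16 granulocyte and mast cell genes 7 rose and 2 fell, the same numbers adjusted over the list alone, and Ltf, a neutrophil granule gene, was among the falling ones at -0.94 (adjusted p = 6.85e-04; adjusted p = 0.0886 with an estimated correlation). Macrophage genes rose in 16 of 17 cases, 16 adjusted over the list alone, with Mpeg1 at 4.85 (adjusted p = 5.57e-10; adjusted p = 0.211 with an estimated correlation). Mitosis genes fell in 26 of 26 cases (26 adjusted over the list alone; median -1.02; adjusted p = 7.59e-10; adjusted p = 0.111 with an estimated correlation). Replication genes fell in 28 of 28, 28 adjusted over the list alone (adjusted p = 3.24e-12; adjusted p = 0.121 with an estimated correlation). Ribosome biogenesis genes fell in 26 of 27, 26 adjusted over the list alone, a call that held with an estimated correlation, with Gnl3 at -1.91. Lysosome and autophagy genes rose in 19 of 26 cases and fell in 1, 19 and 1 adjusted over the list alone, Cd63 by 6.29 (adjusted p = 2.72e-08; adjusted p = 0.166 with an estimated correlation). Limma called 8866 genes, 3898 rising and 4968 falling, and the median change of all genes was -0.147. With the macrophage and the granulocyte and mast cell means as covariates the count was 2691.

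From midpoint to end of this course, the B cell kinase Blk fell by 4.94 ± 0.13 (adjusted p = 4.99e-22), Pcdh9 by 5.02 ± 0.20 and Dock9 by 4.83 ± 0.16, while Tek, a receptor of angiopoietin, rose by 5.10 ± 0.19, Hbb-y, an embryonic globin, by 5.47 ± 0.24 and Sucnr1, the succinate receptor, by 4.90 ± 0.30 (2 arrays against 3). Of 31 pre-B genes 25 fell and 1 rose, 25 and 1 adjusted over the list alone, with Rag1 at -4.62 and Pax5, the transcription factor that maintains B cell identity, at -4.36 (adjusted p = 4.07e-15, held with an estimated correlation). Of 33 fibroblast genes 23 fell and 1 rose, 24 and 1 adjusted over the list alone, Sparc by -1.62 and Col1a1 by -1.46 (adjusted p = 2.79e-04; adjusted p = 0.192 with an estimated correlation). The midpoint arrays were the more compressed ones (mean interquartile range 3.03 against 3.55 at the end), so the size of the fibroblast fall is not exact. Lgals3 differed by -0.50 ± 0.39 (adjusted p = 0.27). Limma called 10871 genes, 5327 rising and 5544 falling, against 4041 and 3864 after quantile normalization. With the fibroblast covariate it called 4173, of which 2771 rose, and 16614 when every probeset was tested.

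**Figure D2:**
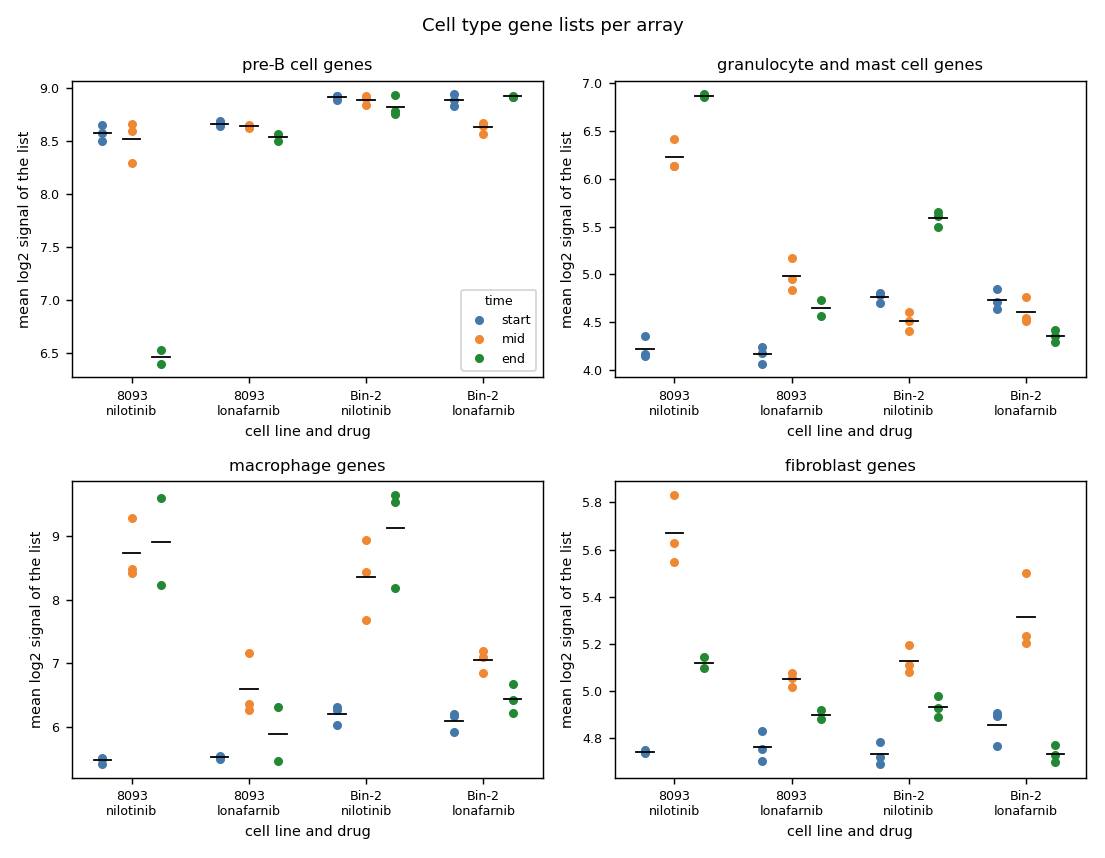
Mean log2 signal of the pre-B, granulocyte and mast cell, macrophage and fibroblast lists (vertical axes) by line and drug (horizontal axes), with a point per array coloured by time and a bar at each group mean. The macrophage mean went from 5.48 to 8.72 and 8.91 in 8093 with nilotinib, while the pre-B mean went from 8.58 to 8.52 and 6.46.

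Lonafarnib in 8093 was followed by a rise of p53 target genes and a fall of cell cycle genes at the midpoint on day 4 (3 arrays against 3). Of 22 measured p53 targets 16 rose and 6 did not pass, 19 adjusted over the list alone, by a median of 0.70 (adjusted p = 7.16e-22, held with an estimated correlation). Eda2r, a receptor of the TNF receptor family, rose by 1.60, the kinase Plk2 by 1.53 and the TRAIL receptor Tnfrsf10b by 1.52. Of 26 mitosis genes 19 fell, 26 adjusted over the list alone, led by the mitotic kinases Plk1 (-1.19) and Aurka (-0.85), and of 28 replication genes 25 fell, 26 adjusted over the list alone, led by Rrm2 (-1.10), a subunit of ribonucleotide reductase. Both calls (adjusted p = 5.50e-20 and 2.70e-23) held with an estimated correlation. Oxidative phosphorylation genes fell in 15 of 25 cases, 22 adjusted over the list alone (adjusted p = 3.70e-14; adjusted p = 0.0801 with an estimated correlation).

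Genes of mast cells and macrophages rose in these arrays too. Cpa3 rose by 5.11 ± 0.26 (adjusted p = 5.38e-14), Mcpt2 by 4.67 ± 0.53 from a start mean of 2.60, at the level of the Y-linked genes, Lyz2 by 5.11 ± 0.53, the chemokine Ccl6 by 4.32 ± 0.46 and Mmp12, the elastase of macrophages, by 4.29 ± 0.42. Among granulocyte and mast cell genes 4 of 16 rose, 5 adjusted over the list alone, a call that held with an estimated correlation, and macrophage genes in 6 of 17, 9 adjusted over the list alone (adjusted p = 5.03e-06; adjusted p = 0.379 with an estimated correlation). Lgals3 rose by 1.90 ± 0.35 (adjusted p = 4.28e-04), Cish by 1.03 ± 0.14 and Bcl2l11 by 0.61 ± 0.12, while Il7r (-1.49 ± 0.16) and Rag1 (-1.69 ± 0.21) fell. Gli3, a transcription factor of Hedgehog signalling, fell (-2.24 ± 0.17), and so did Lin28b, an RNA-binding protein of fetal blood progenitors (-2.18 ± 0.16). Limma called 2150 genes, 775 rising and 1375 falling. The count was 1123 without start replicate 1 and 1252 without midpoint replicate 3, and 851 with the macrophage and the granulocyte and mast cell covariates.

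At the end of the lonafarnib course of 8093 (2 arrays against 3) the p53 targets remained partly raised and Cpa3 stayed high at 4.37 ± 0.29 over the start (adjusted p = 3.03e-11). Of 22 p53 targets 6 rose, 8 adjusted over the list alone, with Eda2r at 1.32 and Psrc1 at 1.25, and the call held with an estimated correlation. S100a6, a calcium-binding protein, rose by 3.08 ± 0.34 and Gimap3, a GTPase of lymphocytes, by 3.07 ± 0.29. Rnase12 fell by 2.93 ± 0.22, Thy1, a surface protein of T cells and some progenitors, by 2.22 ± 0.17 and Pdcd1, the inhibitory receptor PD-1, by 2.20 ± 0.15. Lgals3 differed from the start by 0.18 ± 0.39 (adjusted p = 0.862), and Rhob, a small GTPase that is farnesylated or geranylgeranylated, rose by 0.76 ± 0.14. From start to end Rhob also went from 6.06 to 6.73 in 8093 with nilotinib. In Bin-2 it went from 6.88 to 6.96 with nilotinib and from 6.81 to 6.65 with lonafarnib. Lyz2 rose by 3.48 ± 0.60, but by 2.11 without end replicate 2, where it was not called (adjusted p = 0.0676). The macrophage list was not called at this end. Replication genes fell in 8 of 28 cases, 12 adjusted over the list alone (adjusted p = 1.92e-06; adjusted p = 0.318 with an estimated correlation). Limma called 1737 genes, 877 rising and 860 falling, against 761 and 901 after quantile normalization. The count was 1080 without start replicate 3, 1022 without end replicate 1 and 666 (441 rising and 225 falling) without end replicate 2.

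From midpoint to end of this course the p53 targets came down again, with 8 of 22 falling and 1 rising, 11 and 1 adjusted over the list alone (adjusted p = 6.08e-07, held with an estimated correlation). Plk2 fell by 1.30 on the log2 scale. Mitosis genes rose in 6 of 26 cases, 15 adjusted over the list alone (adjusted p = 5.99e-10; adjusted p = 0.109 with an estimated correlation), and cholesterol synthesis genes in 7 of 20, 10 adjusted over the list alone, with Msmo1 at 0.82 (adjusted p = 9.34e-09; adjusted p = 0.0507 with an estimated correlation). Of 9 MHC class II genes 4 fell and 1 rose, 5 and 1 adjusted over the list alone, with H2-Aa at -2.09 and H2-Ab1 at -1.72 (adjusted p = 3.22e-04; adjusted p = 0.122 with an estimated correlation). Thbs1 fell by 2.45 ± 0.34 and Mcpt2 by 3.48 ± 0.59. Lgals3 fell by 1.72 ± 0.39 (adjusted p = 0.0048), a call lost without end replicate 1 (-1.36, adjusted p = 0.137). Macrophage genes fell in 4 of 17 cases, 6 adjusted over the list alone (adjusted p = 9.04e-04; adjusted p = 0.526 with an estimated correlation), but the list was not called without midpoint replicate 1 (adjusted p = 0.0608) or end replicate 1 (adjusted p = 0.223). Limma called 1248 genes, 788 rising and 460 falling. The count was 823 without midpoint replicate 2, 687 without end replicate 1 and 600 without end replicate 2, and 693 with the macrophage and the granulocyte and mast cell covariates.

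Nilotinib in Bin-2 was followed at the midpoint by a rise of macrophage and MHC class II genes and a fall of cholesterol synthesis genes (3 arrays against 3). Of 17 macrophage genes 14 rose, 15 adjusted over the list alone, by a median of 2.37 (adjusted p = 1.33e-27, held with an estimated correlation), with Lyz2 at 3.83 ± 0.53 and the complement chains C1qc at 3.29 and C1qb at 3.02. Clec4n, the phagocyte lectin dectin-2, rose by 4.17 ± 0.49 and Gpnmb, a glycoprotein of macrophage lysosomes, by 3.80 ± 0.43. Of 9 MHC class II genes 4 rose, 6 adjusted over the list alone, with H2-Aa at 2.63 and Cd74 at 2.28 (adjusted p = 1.39e-09, held with an estimated correlation). Of 20 cholesterol synthesis genes 11 fell and none rose, 15 adjusted over the list alone, by a median of -0.52 (adjusted p = 1.64e-17, held with an estimated correlation). Cyp51, the sterol demethylase, and Idi1, the isomerase of the mevalonate pathway, each fell by 0.87.

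Fibroblast genes rose in 8 of 33 cases in these arrays, 10 adjusted over the list alone, with Fn1 at 2.42 (adjusted p = 2.90e-10, held with an estimated correlation), and Col1a1 rose by 0.62 ± 0.13. Of 20 adhesion and homing genes 6 rose, 10 rising and 1 falling adjusted over the list alone, led by Cd9 (2.12) and Cd44 (1.68), and this call held too. Of 26 lysosome and autophagy genes 9 rose, 10 adjusted over the list alone, with Cd63 at 2.22 (adjusted p = 9.05e-10; adjusted p = 0.121 with an estimated correlation). Lgals3 rose by 2.33 ± 0.35 (adjusted p = 6.39e-05). Gria2 fell by 3.21 ± 0.29, the cadherin Cdh17 by 2.31 ± 0.28 and the adhesion protein Epcam by 1.70 ± 0.22. The granulocyte and mast cell list went down here, with Ctsg at -1.63 and Mcpt8 at -1.32 as its 2 falling members of 16, 2 adjusted over the list alone (adjusted p = 0.0103; adjusted p = 0.197 with an estimated correlation). Limma called 692 genes, 372 rising and 320 falling. The count was 422 without start replicate 2, 438 without start replicate 3 and 342 without midpoint replicate 1, 357 with the fibroblast covariate, and 71 (20 rising and 51 falling) with the macrophage and the granulocyte and mast cell covariates.

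At the end of nilotinib in Bin-2 macrophage and MHC class II genes lay above the start, as did the mast cell genes Fcer1a and Cpa3 (3 arrays against 3). All 17 macrophage genes rose, 17 adjusted over the list alone, by a median of 3.18 (adjusted p = 1.68e-32, held with an estimated correlation). Of 9 MHC class II genes 7 rose, 8 adjusted over the list alone, with H2-Aa at 4.76 and Cd74 at 4.23, and H2-Ea, an MHC class II chain that some mouse strains do not express, rose by 5.25 ± 0.21 (adjusted p = 1.37e-16). Fcer1a rose by 5.39 ± 0.35 and Cpa3 by 4.98 ± 0.26 (adjusted p = 5.24e-14), from 6.50 to 11.48. Of 20 cholesterol synthesis genes 16 fell, 16 adjusted over the list alone, by a median of -0.65 (adjusted p = 2.70e-18, held with an estimated correlation), with Hsd17b7 at -1.19 and Insig1, the regulator of the sterol sensor, at -1.17.

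Beside the macrophage genes, 8 of 18 NRF2 target genes rose, 10 adjusted over the list alone, with Hmox1, haem oxygenase, at 2.83 (adjusted p = 1.93e-10, held with an estimated correlation). Lysosome and autophagy genes rose in 12 of 26 cases, 16 adjusted over the list alone, Cd63 by 3.99 (adjusted p = 6.25e-14; adjusted p = 0.0626 with an estimated correlation). Granulocyte and mast cell genes rose in 5 of 16 cases and fell in 2, 6 and 2 adjusted over the list alone (adjusted p = 0.00796; adjusted p = 0.187 with an estimated correlation). The pre-B list was not called at this end, with means of 8.91 at the start and 8.83 at the end. Lgals3 rose by 3.71 ± 0.35 (adjusted p = 7.53e-09) and Bcl6 by 0.99 ± 0.19, while Myc (-0.01 ± 0.15) and Bcl2l11 (0.16 ± 0.12) were not called. Gria2 fell by 3.18 ± 0.29 and Ica1 by 2.15 ± 0.16. Limma called 1772 genes, 987 rising and 785 falling. The count was 1120 without end replicate 1, and 37 with the macrophage and the granulocyte and mast cell covariates.

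Between midpoint and end of this course some mast cell genes rose steeply (3 arrays against 3). Cpa3 rose by 5.68 ± 0.26 (adjusted p = 3.03e-15), Fcer1a by 4.99 ± 0.35 and Cyp11a1 by 4.04 ± 0.25. Granulocyte and mast cell genes rose in 5 of 16 cases, 5 adjusted over the list alone, and MHC class II genes in 5 of 9, 6 adjusted over the list alone, with H2-Aa at 2.13. Both calls (adjusted p = 9.01e-11 and 3.75e-14) held with an estimated correlation. The macrophage list shifted up by a median of 0.75 with 0 of 17 genes called, 6 adjusted over the list alone (adjusted p = 1.05e-09; adjusted p = 0.219 with an estimated correlation). Lgals3 rose by 1.38 ± 0.35 (adjusted p = 0.0351), but was not called without midpoint replicate 2 (0.99, adjusted p = 0.37), midpoint replicate 3 (1.41, adjusted p = 0.0974), end replicate 1 (0.98, adjusted p = 0.404) or end replicate 2 (1.24, adjusted p = 0.217). Limma called 282 genes, 199 rising and 83 falling. The count was 134 and 169 without midpoint replicates 2 and 3, and 119, 127 and 582 without end replicates 1, 2 and 3. It was 158 in a fit to the arrays of this course alone, and 60 with the macrophage and the granulocyte and mast cell covariates.

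**Figure D3:**
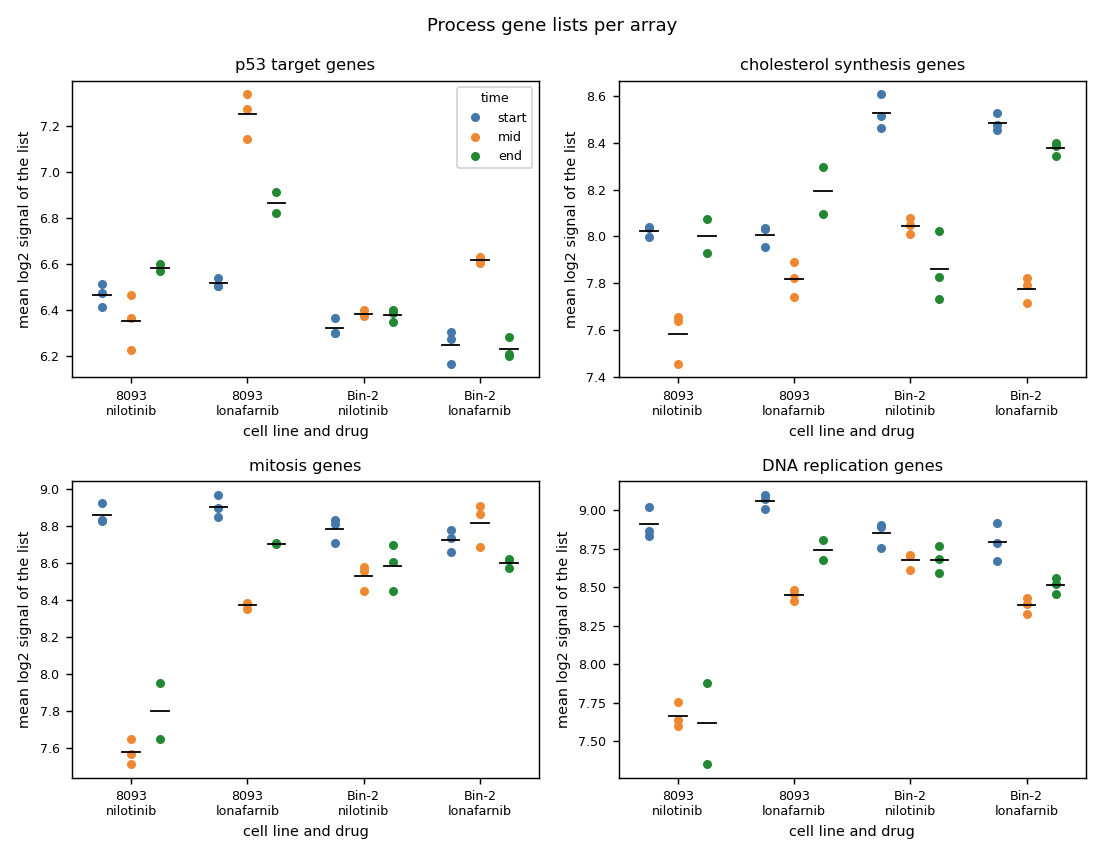
Mean log2 signal of the p53 target, cholesterol synthesis, mitosis and DNA replication lists (vertical axes) by line and drug (horizontal axes), with a point per array coloured by time and a bar at each group mean. From start to midpoint the p53 list changed by a mean of 0.74 in 8093 with lonafarnib and the cholesterol list by -0.71 in Bin-2 with lonafarnib.

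In Bin-2 with lonafarnib every measured gene of cholesterol synthesis was lower at the midpoint than at the start (3 arrays against 3). All 20 fell, 20 adjusted over the list alone, by a median of -0.70 (adjusted p = 1.23e-17, held with an estimated correlation), with Insig1 at -1.15, the lanosterol synthase Lss at -1.01 and the squalene synthase Fdft1 at -0.89, and Scd1, which desaturates fatty acids, fell by 1.55 ± 0.24. Fibroblast genes rose in 14 of 33 cases, 18 adjusted over the list alone, with Fn1 at 2.52, Col1a1 at 1.22 ± 0.13 and Sparc at 0.91 (adjusted p = 1.19e-10, held with an estimated correlation). Of 22 p53 targets 8 rose, 12 rising and 1 falling adjusted over the list alone, with Zmat3 at 1.14 and Psrc1 at 1.07 (adjusted p = 6.30e-07, held with an estimated correlation). Macrophage genes rose in 7 of 17 cases, 8 adjusted over the list alone, with Lyz2 at 3.20 ± 0.53 (adjusted p = 8.93e-05; adjusted p = 0.443 with an estimated correlation). Mmp12 rose by 3.61 ± 0.42, Gpnmb by 3.51 ± 0.43 and Lgals3 by 2.23 ± 0.35 (adjusted p = 8.77e-05).

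Genes of energy metabolism and replication fell at the same midpoint. The mean interquartile range was 3.16 here against 3.43 at the start, so the size of falls of bright genes is not exact. The same holds for rises of dim genes, among them the fibroblast list with a start mean of 4.86. Oxidative phosphorylation genes fell in 18 of 25 cases, 22 adjusted over the list alone, with Ndufb8 at -0.83 (adjusted p = 3.34e-11; adjusted p = 0.121 with an estimated correlation), and replication genes in 16 of 28, 19 adjusted over the list alone, with Gins1 at -0.89 and Rrm2 at -0.88 (adjusted p = 5.49e-09; adjusted p = 0.197 with an estimated correlation). Pre-B genes fell in 8 of 31 cases, 10 falling and 1 rising adjusted over the list alone, with Vpreb3 at -0.86 and Cd24a at -0.82 (adjusted p = 0.00147; adjusted p = 0.359 with an estimated correlation). With the fibroblast covariate that list was not called (mean -0.03, adjusted p = 0.368). Il1r2, a decoy receptor of interleukin-1 (-1.40 ± 0.14), and Ctsg, a granule protease (-1.29 ± 0.23), fell. Limma called 3287 genes, 887 rising and 2400 falling, so that 27.0% rose. When every probeset was tested, 5064 were called and 39.5% of them rose. The count was 1930 without midpoint replicate 2, 1975 after quantile normalization, 960 with the fibroblast covariate, 2183 with the macrophage and the granulocyte and mast cell covariates and 5812 against the start arrays of both courses.

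At the end of lonafarnib in Bin-2 the ubiquitin ligase Nedd4 was far below its start level (-3.32 ± 0.13, adjusted p = 1.05e-17; 3 arrays against 3). Cdh17 fell by 3.45 ± 0.28, the chemokine receptor Ccr2 by 3.06 ± 0.29 and the actin-severing protein Scin by 2.98 ± 0.17. Gca, a calcium-binding protein, rose by 3.25 ± 0.18, Vat1l by 3.11 ± 0.19, the transcriptional coactivator Eya1 by 2.83 ± 0.23, Myzap by 2.80 ± 0.11 and Mmp12 by 2.98 ± 0.42. Cish rose by 1.00 ± 0.14, Bcl2l11 by 0.74 ± 0.12 and Socs2, also a STAT5 target, by 0.64 ± 0.11. Lgals3 rose by 1.27 ± 0.35 (adjusted p = 0.0168), but was not called without start replicate 1 (1.24, adjusted p = 0.0615), start replicate 3 (1.23, adjusted p = 0.0576), end replicate 2 (1.11, adjusted p = 0.0965) or end replicate 3 (1.20, adjusted p = 0.0693). Of 16 granulocyte and mast cell genes 4 fell, 4 falling and 1 rising adjusted over the list alone, with the stem cell factor receptor Kit at -2.44 and Ctsg at -1.94 (adjusted p = 0.00559; adjusted p = 0.161 with an estimated correlation). Lysosome and autophagy genes rose in 9 of 26 cases, 12 adjusted over the list alone, with Ctsl at 2.18 and Npc1, the lysosomal cholesterol exporter, at 0.86 (adjusted p = 1.95e-07; adjusted p = 0.192 with an estimated correlation). Replication genes fell in 7 of 28 cases, 12 adjusted over the list alone, Rrm2 by 0.89 on the log2 scale (adjusted p = 1.06e-07; adjusted p = 0.253 with an estimated correlation). The macrophage list was not called. Limma called 1608 genes, 929 rising and 679 falling, against 738 and 780 after quantile normalization.

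From midpoint to end of this course cholesterol synthesis genes rose, with 19 of 20 rising, 19 adjusted over the list alone, among them the squalene epoxidase Sqle (0.81) and Fdft1 and Lss (0.80 each; adjusted p = 6.68e-09; adjusted p = 0.0505 with an estimated correlation). At the end their list was still below the start, with 1 of 20 falling, 1 adjusted over the list alone (mean -0.11, adjusted p = 0.0457; adjusted p = 0.508 with an estimated correlation). That call was lost without start replicate 3 (adjusted p = 0.174) or end replicate 3 (adjusted p = 0.125). Fibroblast genes fell in 18 of 33 cases, 20 adjusted over the list alone, with Thbs1 at -2.70, Fn1 at -1.98 and Col1a1 at -1.45 ± 0.13 (adjusted p = 7.31e-10, held with an estimated correlation). The midpoint arrays were the more compressed ones (mean interquartile range 3.16 against 3.47 at the end). The size of this fall and of the rise of cholesterol synthesis genes is therefore not exact. Of 22 p53 targets 8 fell and 3 rose, 9 and 3 adjusted over the list alone, with Psrc1 at -1.64 and Plk2 at -1.62 (adjusted p = 6.30e-04; adjusted p = 0.0754 with an estimated correlation). Pre-B genes rose in 13 of 31 cases and fell in 1, 13 and 2 adjusted over the list alone, with Spib at 1.42 and Cd79a, a signalling chain of the B cell receptor, at 0.99 (adjusted p = 0.0105; adjusted p = 0.443 with an estimated correlation). With the fibroblast covariate the pre-B list was not called (mean 0.04, adjusted p = 0.351). Gimap3 rose by 3.49 ± 0.26 and Jchain, the joining chain of antibodies, by 3.48 ± 0.12, while Cdh17 fell by 3.80 ± 0.28. In the same arrays the mean of the macrophage list went from 7.05 to 6.43 and Lgals3 from 8.19 to 7.23. The macrophage list was called, but not without midpoint replicate 1 (mean -0.54, camera adjusted p = 0.0657). Limma called 5926 genes, 3939 rising and 1987 falling, and 2149 with the fibroblast covariate.

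Genes that changed alike in all 4 courses were counted to find what both drugs and both lines had in common. At the midpoint 42 genes rose and 55 fell in every course, where independent lists of the same sizes would share 0.145 and 0.731. All 4 lists used the same estimate of each gene's spread, so they were not independent. The excess over these numbers therefore does not by itself measure agreement between courses. After quantile normalization 39 rose and 27 fell, and in a fit to the arrays of the courses compared 65 rose and 35 fell, so which direction was more frequent depended on the fit. Lyz2 rose by 7.67, 5.11, 3.83 and 3.20 in 8093 with nilotinib, 8093 with lonafarnib, Bin-2 with nilotinib and Bin-2 with lonafarnib. In the same order Mmp12 rose by 6.07, 4.29, 3.49 and 3.61 and Clec4n by 6.68, 4.19, 4.17 and 3.36. Gpnmb, Ccl6, Wfdc17 and the receptors Lilr4b and Lilrb4a, all expressed by myeloid cells, completed the leading 8. Among the falling genes Pcbd1, a dehydratase that recycles the tetrahydrobiopterin cofactor, changed by -1.98, -0.89, -0.94 and -0.89, and Scd2, a fatty acid desaturase, by -1.52, -0.69, -0.76 and -1.15. A further 9 genes were called in all 4 courses with mixed directions. Over the other 3 courses, without nilotinib in 8093, 42 genes rose and 56 fell. The count of 97 was 61 without the lonafarnib start replicate 1 of 8093, 63 (39 rising and 24 falling) without the nilotinib midpoint replicate 1 of Bin-2, 45 (25 and 20) with the fibroblast covariate, and 1 with the macrophage and the granulocyte and mast cell covariates.

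At the end 29 genes rose and 25 fell in every course, against 0.395 and 0.287 for independent lists, and 58 more were called with mixed directions. With 58 of the 112 genes called in all 4 courses mixed in direction, the excess over independent lists does not by itself measure agreement. Mmp12 rose by 5.68, 2.74, 4.94 and 2.98 and Wfdc17 by 4.83, 3.02, 4.81 and 2.61 in the same order of courses, and the chemokine Ccl3 by 4.80, 2.67, 4.29 and 1.90. Pcbd1 changed by -1.83, -1.07, -1.25 and -2.73, Thy1 by -3.33, -2.22, -1.01 and -1.26, and Jag2, a ligand of Notch receptors, by -3.48, -0.80, -0.97 and -0.81. Without end replicate 2 of 8093 with lonafarnib the count of 54 was 26. In that course Mmp12 was then at 1.80 (adjusted p = 0.0591), Wfdc17 at 1.71 (adjusted p = 0.211), Ccl3 at 1.61 (adjusted p = 0.109) and Pcbd1 at -0.91 (adjusted p = 0.0642), and none of the 4 was called there. With the macrophage and the granulocyte and mast cell covariates 1 gene was left. These covariates cost precision, so the counts of 1 at midpoint and end do not show what accounts for the other genes.

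**Figure D4:**
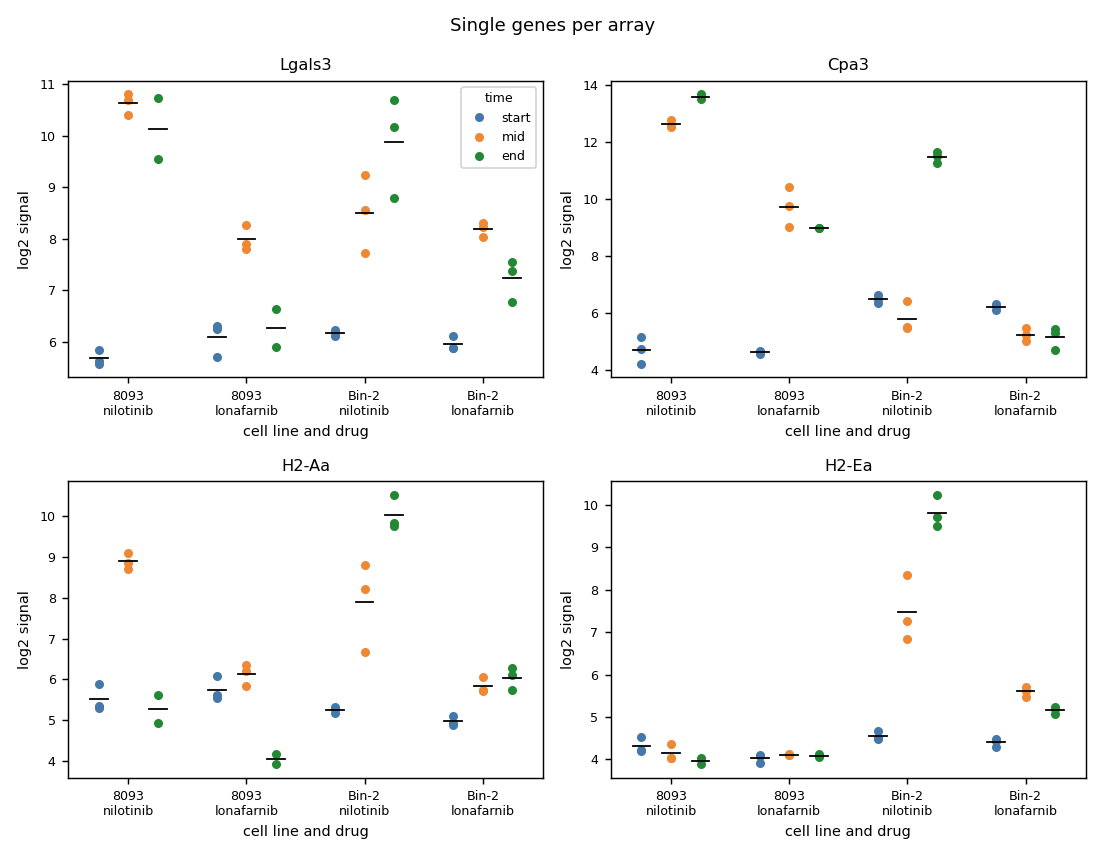
Log2 signal of Lgals3, Cpa3, H2-Aa and H2-Ea (vertical axes) by line and drug (horizontal axes), with a point per array coloured by time and a bar at each group mean. Lgals3 went from 5.68 to 10.64 and 10.14 in 8093 with nilotinib and from 6.09 to 7.99 and 6.27 in 8093 with lonafarnib.

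The drugs were then compared within 8093 by testing the difference of their changes from the start (nilotinib minus lonafarnib), although doses were chosen per line and midpoints fell on days 3 and 4. Viability at these midpoints was 5 to 10% with nilotinib and 20% with lonafarnib, so drug and viability cannot be told apart. The ends with nilotinib and lonafarnib fell on days 20 and 26 in 8093 and on days 21 and 30 in Bin-2. At the midpoint the difference was positive for mast cell genes and negative for genes of ribosome biogenesis and p53 targets. Cyp11a1 differed by 3.94 ± 0.36 (adjusted p = 1.17e-08), Mcpt1 by 4.28 ± 0.64 and Lgals3 by 3.05 ± 0.49, and Rasgrp3 differed by -3.85 ± 0.38 and Bcl2l11 by -1.31 ± 0.18. Among granulocyte and mast cell genes 7 of 16 differed upwards and 1 downwards, 8 and 1 adjusted over the list alone, with Ms4a2 at 3.82. Ribosome biogenesis genes differed downwards in 22 of 27, 26 adjusted over the list alone, with Utp4 at -1.61, and p53 targets in 13 of 22, 14 adjusted over the list alone, with Zmat3 at -2.07. These 3 calls (adjusted p = 3.50e-06, 1.30e-14 and 3.08e-08) held with an estimated correlation. The nilotinib midpoint arrays were more compressed (mean interquartile range 3.03 against 3.42 with lonafarnib). The size of differences of bright lists such as ribosome biogenesis is therefore not exact. Macrophage genes differed upwards in 15 of 17 cases, 15 adjusted over the list alone (adjusted p = 1.00e-09; adjusted p = 0.22 with an estimated correlation). Limma called 5334 genes, 1832 upwards and 3502 downwards, 8070 when every probeset was tested, 2330 with the fibroblast covariate and 488 with the macrophage and the granulocyte and mast cell covariates.

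At the end (2 arrays in each end group) pre-B genes lay far lower with nilotinib than with lonafarnib, 23 of 31 downwards and 3 upwards, 23 and 3 adjusted over the list alone, with Dntt, the terminal transferase of early lymphocytes, at -5.16 and the B cell transcription factor Ebf1 at -4.38 (adjusted p = 6.73e-14, held with an estimated correlation). Ms4a2 differed by 7.72 ± 0.52, Cyp11a1 by 7.47 ± 0.40 (adjusted p = 4.29e-15) and the amino acid transporter Slc7a8 by 7.63 ± 0.48, while Gria2 differed by -6.87 ± 0.45 and Gimap4 by -5.64 ± 0.19. Lgals3 differed by 4.27 ± 0.55, Cish by 1.87 ± 0.22, Socs2 by -2.02 ± 0.18 and Il7r by -1.67 ± 0.26. Macrophage genes differed upwards in 16 of 17 cases, 16 adjusted over the list alone (adjusted p = 1.20e-08; adjusted p = 0.254 with an estimated correlation). Limma called 6612 genes, 3138 upwards and 3474 downwards, against 3160 and 3150 after quantile normalization, and 2157 with the macrophage and the granulocyte and mast cell covariates.

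In Bin-2 the same difference at the midpoint was positive for Siglech, a lectin of plasmacytoid dendritic cells and microglia (2.28 ± 0.19, adjusted p = 2.52e-08), and for Csf1r, the macrophage growth factor receptor (2.54 ± 0.47), and negative for Cdh17 (-2.66 ± 0.40) and Gria2 (-2.64 ± 0.40). Of 22 p53 targets 4 differed downwards, 7 adjusted over the list alone, with Zmat3 at -1.41 and Psrc1 at -1.16, and of 9 MHC class II genes 3 upwards, 7 adjusted over the list alone. Both calls (adjusted p = 1.01e-05 and 8.12e-07) held with an estimated correlation. Macrophage genes differed upwards in 3 of 17 cases, 7 adjusted over the list alone (adjusted p = 2.69e-07; adjusted p = 0.31 with an estimated correlation). Lgals3 differed by 0.10 ± 0.49 (adjusted p = 0.963). Limma called 295 genes, of which 70.2% differed upwards, and 40.6% of 613 when every probeset was tested. The count was 153 and 162 without nilotinib start replicates 1 and 2, 159 without nilotinib midpoint replicate 1, 162 without lonafarnib start replicate 2, and 138 with the macrophage and the granulocyte and mast cell covariates.

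At the end in Bin-2 the difference was positive for Cpa3 (6.06 ± 0.36, adjusted p = 9.57e-13), Fcer1a (5.48 ± 0.49) and Ppbp, a platelet chemokine (4.88 ± 0.72). Of 16 granulocyte and mast cell genes 6 differed upwards, 6 upwards and 3 downwards adjusted over the list alone (adjusted p = 8.38e-05; adjusted p = 0.0557 with an estimated correlation). Gria2 differed by -5.64 ± 0.40 and Gimap3 by -4.35 ± 0.37. MHC class II genes differed upwards in 6 of 9 cases, 7 adjusted over the list alone, with H2-Aa at 3.70, and adhesion and homing genes in 9 of 20 with 1 downwards, 9 and 1 adjusted over the list alone, with Cd34 at 2.94. Both calls (adjusted p = 8.35e-10 and 2.26e-06) held with an estimated correlation. Cholesterol synthesis genes differed downwards in 11 of 20 cases, 14 adjusted over the list alone, with Hsd17b7 at -1.26 (adjusted p = 4.53e-08; adjusted p = 0.0638 with an estimated correlation). Macrophage genes differed upwards in 16 of 17 cases, 17 adjusted over the list alone (adjusted p = 4.88e-19; adjusted p = 0.0669 with an estimated correlation). Lgals3 differed by 2.44 ± 0.49 (adjusted p = 0.00113). Limma called 1896 genes, 927 upwards and 969 downwards, against 954 and 703 after quantile normalization, and 242 with the macrophage and the granulocyte and mast cell covariates.

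The lines were compared in the same way (Bin-2 minus 8093), with doses that differed between them. With lonafarnib the midpoint was day 3 at 5 to 10% viability in Bin-2 and day 4 at 20% in 8093. The lonafarnib ends were days 30 and 26. Line, dose, day and viability cannot be told apart there. Under nilotinib at the midpoint, mast cell genes differed downwards and growth genes upwards. Cpa3 differed by -8.62 ± 0.36 (adjusted p = 4.55e-16), Mcpt2 by -8.06 ± 0.75 and Lgals3 by -2.63 ± 0.49, while Rasgrp3 differed by 5.28 ± 0.38, the metallothionein Mt2 by 3.69 ± 0.48 and Bcl2l11 by 1.06 ± 0.18. Granulocyte and mast cell genes differed downwards in 9 of 16 cases, 11 adjusted over the list alone, mitosis genes upwards in 25 of 26, 25 adjusted over the list alone, and ribosome biogenesis genes upwards in 24 of 27, 27 adjusted over the list alone. These 3 calls (adjusted p = 7.99e-12, 2.78e-16 and 4.02e-14) held with an estimated correlation. The midpoint arrays of 8093 were more compressed (mean interquartile range 3.03 against 3.45 in Bin-2). Bright lists differ upwards through this alone, so the size of the mitosis and ribosome biogenesis differences is not exact. Limma called 5188 genes, 3591 upwards and 1597 downwards, 7806 when every probeset was tested, and 637 with the macrophage and the granulocyte and mast cell covariates.

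Under nilotinib at the end pre-B genes differed upwards in 25 of 31 cases and downwards in 2, 26 and 2 adjusted over the list alone, with Rag1 at 4.81 and Vpreb1 at 4.16 (adjusted p = 4.10e-17), and ribosome biogenesis genes upwards in 26 of 27, 26 adjusted over the list alone (adjusted p = 1.94e-11). Both calls held with an estimated correlation. H2-Ea differed by 5.60 ± 0.32 and Cd74 by 5.03 ± 0.42, Il7r by 2.49 ± 0.25, Socs2 by 2.21 ± 0.17 and Bcl2l11 by 2.42 ± 0.19. Of 16 granulocyte and mast cell genes 8 differed downwards and 1 upwards, 8 and 1 adjusted over the list alone, with Kit at -5.67 (adjusted p = 5.42e-05; adjusted p = 0.0518 with an estimated correlation). Nrn1 differed by -6.33 ± 0.30, Igfbp5, a binding protein of insulin-like growth factors, by -6.10 ± 0.29, and Lgals3 by -0.75 ± 0.52 (adjusted p = 0.312). Limma called 6104 genes, 3120 upwards and 2984 downwards.

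Under lonafarnib at the midpoint the lines differed in cell cycle, cholesterol and STAT5 target genes. Mitosis genes differed upwards in 14 of 26 cases, 21 adjusted over the list alone, with Plk1 at 1.15, cholesterol synthesis genes downwards in 4 of 20, 13 adjusted over the list alone, with Tm7sf2 at -1.23, and STAT5 targets downwards in 5 of 22, 6 adjusted over the list alone, with Pim2 at -1.39 and Cish at -1.19 ± 0.20. These 3 calls (adjusted p = 5.56e-22, 1.76e-09 and 4.01e-04) held with an estimated correlation. Here the Bin-2 midpoint arrays were more compressed (mean interquartile range 3.16 against 3.42 in 8093), so the size of downward differences of bright lists is not exact. Cpa3 differed by -6.09 ± 0.36 (adjusted p = 5.02e-12), Gli3 by 2.37 ± 0.24, Lin28b by 2.19 ± 0.22, Col1a1 by 1.14 ± 0.18, and Lgals3 by 0.33 ± 0.49 (adjusted p = 0.806). Limma called 838 genes, 168 upwards and 670 downwards, against 215 and 470 after quantile normalization. The count was 530 without lonafarnib start replicate 3 of 8093 and 516 without its midpoint replicate 1.

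Under lonafarnib at the end p53 targets differed downwards in 7 of 22 cases and upwards in 2, 7 and 2 adjusted over the list alone, with Psrc1 at -1.82, Eda2r at -1.66 and Btg2, an antiproliferative gene, at 1.43 (adjusted p = 4.58e-05, held with an estimated correlation). Myzap differed by 3.99 ± 0.16 (adjusted p = 7.44e-17), Vat1l by 2.97 ± 0.29 and Bcl2l11 by 1.30 ± 0.19, and Cpa3 differed by -5.45 ± 0.39, Cdh17 by -4.14 ± 0.42, the mucin Muc13 by -3.87 ± 0.22 and Rhob by -0.92 ± 0.19. Granulocyte and mast cell genes differed downwards in 5 of 16 cases, 5 adjusted over the list alone (adjusted p = 1.27e-04; adjusted p = 0.0636 with an estimated correlation). Limma called 920 genes, 423 upwards and 497 downwards, and 566 without end replicate 2 of 8093.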

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

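The tests of mast cell genes, mislabelled arrays, H2-Ea, the arrangement of arrays in large splits, and macrophages and mast cells alone as the source of Lgals3 were chosen after the results were seen.

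In all 8 comparisons of changes between drugs or lines, the difference itself passed the test for many genes. Nilotinib and lonafarnib differed in 5334 genes at the midpoint and 6612 at the end in 8093, and in 295 and 1896 in Bin-2. The lines differed in 5188 genes at the midpoint and 6104 at the end with nilotinib, and in 838 and 920 with lonafarnib. In 100 splits that exchanged arrays between the courses at each time, the real one included, 5 gave as many genes for the drugs at the midpoint of 8093 (highest other 6574), 8 at the midpoint of Bin-2 (1219) and 3 at its end (2072). For the lines 5 did with nilotinib at the midpoint (6698) and 7 with lonafarnib (5474). These splits leave open whether chance can be excluded, because exchanging the courses at one time alone keeps their difference at the other time in the comparison. For the drugs all 4, 7 and 2 other splits as large kept or exchanged the courses whole at the later time, and for the lines 4 of 4 and 3 of 6. The highest others of 1219 against 295 and 5474 against 838 are several times the real count. In these 2 comparisons 4 of 7 and 6 of 6 other splits as large exchanged 2 or 3 more arrays at 1 time than at the other. Such an exchange can by itself give large counts. For genes changed alike at the midpoint 1 of 100 splits, the real one, reached 97 (highest other 0). Other splits within a course called at most 7 genes at the midpoint, so this count does not test agreement between courses.

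With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In each of the 8 comparisons over time of this size 1 split of 10 was as large, the real one. Real counts and the highest other were 9988 and 2 (8093, nilotinib, midpoint), 2150 and 0 (8093, lonafarnib, midpoint), 692 and 0, 1772 and 1, and 282 and 199 (Bin-2, nilotinib, midpoint, end, and end against midpoint), and 3287 and 7, 1608 and 2, and 5926 and 1 (Bin-2, lonafarnib, in the same order). For the start arrays 10 of 10 splits were as large, with 0 real and at most 1 (8093) and 0 (Bin-2) otherwise by limma, 2350 and 1085 genes at an unadjusted p below 0.05, and 17 and 0 with a trended, robust prior.

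Pre-B genes were low and mast cell genes high at the nilotinib end of 8093. After quantile normalization the mean change of the pre-B list was -2.11, so differences in the distribution of the deposited values between arrays do not account for it. This step was applied on top of the authors' normalization and cannot undo it, so that normalization as the cause stays open. For the mast cell genes, mislabelled arrays are argued against by the 9 of 16 granulocyte and mast cell genes that had risen already at the midpoint of the same course. For the pre-B genes this count decides nothing, since their list mean was 8.52 at the midpoint and 6.46 at the end. RNA from cells of another type stays open: 6 of 7 mast cell or basophil genes rose (all but Mcpt8), which restates the pattern and decides nothing about its source. A change of lineage of the leukaemia cells was not tested and stays open.

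Macrophage genes and Lgals3 were high at the midpoint in 4 courses. RNA from the fibroblast feeder as the whole source stays open. Lgals3 stayed called in 4 of 4 courses with the fibroblast covariate (5.33, 2.00, 2.50 and 2.47). Its relation to the fibroblast list within groups was weak (r = 0.168, permutation p = 0.235, rho = 0.324, permutation p = 0.0815, r = 0.267 without the 2 farthest arrays). Both results rest on small differences of the fibroblast list among the arrays of a group, so neither can decide. In 8093 with nilotinib the SE of the Lgals3 change went from 0.35 to 0.76 with this covariate. RNA from macrophages stays open: within groups over 34 arrays Lgals3 followed the macrophage list (r = 0.862, permutation p = 4.3e-04, adjusted 8.6e-04; rho = 0.795, permutation p = 1.8e-04, adjusted 3.6e-04; r = 0.801 without the 2 farthest arrays; 2 relations computed). RNA from macrophages and mast cells alone stays open as well. With both covariates the rise stayed called in 3 of 4 courses (4.96 to 3.19, 1.90 to 1.38 and 2.23 to 1.58). In Bin-2 with nilotinib it went from 2.33 (SE 0.35) to 0.49 (SE 0.27, adjusted p = 0.553), where the smaller change ended the call. The covariate slopes rest on differences among the 2 or 3 arrays of a group. They may therefore remove too little of a larger rise between groups, and the remaining rise decides nothing about its source. A rise of Lgals3 in the leukaemia cells was not tested separately and may add to it.

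MHC class II genes were high at the midpoint with nilotinib in both lines, with H2-Aa up by 3.37 in 8093 and 2.63 in Bin-2. RNA from a feeder shared by both lines is argued against for H2-Ea alone, whose change differed by 3.09 (SE 0.30, 95% interval 2.48 to 3.70) between the lines. For the other genes it stays open, since a feeder that does not express H2-Ea could still supply them. By limma the changes of H2-Aa (-0.74, adjusted p = 0.229), H2-Eb1 (-0.68, adjusted p = 0.0655) and Cd74 (0.18, adjusted p = 0.783) were not called as different between the lines. RNA from cells of each line's own genotype stays open: H2-Ea, which C57BL/6 mice do not express, changed by -0.17 in 8093 (95% interval -0.60 to 0.27) and by 2.92 in Bin-2. The strain of the feeder is not stated in the labels, and a feeder batch per line and the leukaemia cells' own MHC class II genes were not tested and stay open.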

How the results depend on the processing

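The macrophage and mast cell covariates were chosen after seeing the data, as were the 3 courses without nilotinib in 8093, quantile normalization of lists, and leave-one-out for lists and genes changed alike. Self-test recovery at 1.5-fold limits what 2 or 3 arrays can show. Covariates that differ between the groups compared cost precision, so a lower count with them does not show its source. Of 1023 called values of named genes over time, 20 had a lower group mean at or below 3.32, the highest group mean of Y-linked genes, so the size of these changes and of differences built on them is not exact. The replicate block was not run for the start arrays, since a block lies within a course. Replicate numbers correlated above 0.1 in 2 of 32 pairs of arrays and letters in 4 of 32, so arrays were not paired. Quantile normalization shifted the median of all genes by -0.046 to 0.0546. Where a count moved by more than 1.5 times the cause was not tested, except that testing every probeset adds tests and leave-one-out fits have fewer arrays.

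Testing all probesets gave 15864 (8093 nilotinib midpoint), 16614 (end against midpoint), 5064 (Bin-2 lonafarnib midpoint), 8070 and 613 (drugs at the midpoint in 8093 and Bin-2) and 7806 (lines, nilotinib midpoint). The fibroblast covariate gave 3861 (8093 nilotinib midpoint), 4173 (end against midpoint), 357 (Bin-2 nilotinib midpoint), 960 (Bin-2 lonafarnib midpoint), 2149 (end against midpoint), 2330 (drugs, 8093 midpoint), 2 (8093 starts) and 45 (alike, midpoint). At the Bin-2 lonafarnib midpoint quantile normalization gave 1975 and the start arrays of both courses 5812. Only arrays of the courses compared gave 158 (Bin-2 nilotinib, end against midpoint) and 3 (8093 starts), where trend and robust gave 17 and leaving out dim genes 1. The replicate block gave 188 for the drugs at the Bin-2 midpoint. With an estimated inter-gene correlation 27 of 288 tests of gene lists over time were called, against 141 with the preset one.

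The macrophage and mast cell covariates gave 759 and 2691 (8093 nilotinib midpoint and end), 851 and 693 (8093 lonafarnib midpoint, and end against midpoint), 71, 37 and 60 (Bin-2 nilotinib midpoint, end, and end against midpoint), 2183 (Bin-2 lonafarnib midpoint), 488 and 2157 (drugs in 8093), 138 and 242 (drugs in Bin-2), 637 (lines, nilotinib midpoint), and 1 and 1 (alike, midpoint and end).

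Leave-one-out counts ran from 1123 to 1766, 666 to 1358 and 600 to 1089 (8093 lonafarnib midpoint, end, and end against midpoint), 342 to 619, 1120 to 2170 and 119 to 582 (Bin-2 nilotinib, same order), 1930 to 3302 (Bin-2 lonafarnib midpoint), 0 to 198 (8093 starts), 153 to 288 (drugs, Bin-2 midpoint), 516 to 890 and 566 to 922 (lines with lonafarnib, midpoint and end), and 61 to 113 and 26 to 64 (alike, midpoint and end). Of single-gene values 12328 kept direction and side of the threshold without 1 array and 1106 lost the call, and of list values 3516 and 103.

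Single-gene and list values that were called in the main or the other fit changed direction only with the fibroblast covariate, and the cause was not tested. Values called in neither fit changed direction with other settings too. In leave-one-out fits these were 117 single-gene and 155 list values, and after quantile normalization 20 and 42. The pre-B list mean was 0.29 and 0.14 at the nilotinib midpoints of 8093 and Bin-2 (from -0.0585 and -0.0222), and 0.22 between drugs at the 8093 midpoint (from -0.0377). In these 3 the list was not called without the covariate and was called upwards with it (adjusted p = 0.00111, 0.00294 and 0.00433). In 3 list values of Bin-2 with lonafarnib the mean shrank but kept its sign, and only the direction of the camera test turned, with no call. The pre-B list mean went from -0.26 to -0.0321 at the midpoint and from 0.29 to 0.0361 from midpoint to end, and the FOXO list mean from 0.30 to 0.12 from midpoint to end. At the 8093 nilotinib midpoint Bik was at -0.63, Cd3d at -0.0816, Cd8a at -0.50, Nupr1 at -0.14 and Col3a1 at -0.42, and from midpoint to end Nusap1 at -0.37, Cd8a at 0.14 and Col3a1 at 0.10. In Bin-2 with lonafarnib Dkc1 was at 0.10 (midpoint), and Klf2 at 0.12, Col3a1 at 0.19 and Il7r at -0.0514 (end against midpoint).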

Other observations

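Several gene lists outside the accounts above also moved. At the nilotinib end of 8093 (2 arrays against 3), 13 of 18 NRF2 targets rose and 2 fell, 13 and 2 adjusted over the list alone, with Me1 at 4.77 and Slc7a11 at 4.35 (adjusted p = 1.08e-05; adjusted p = 0.14 with an estimated correlation). Of 16 ABC transporters 10 rose and 3 fell, 10 and 4 adjusted over the list alone, with the drug efflux pump Abcb1b at 3.08 (adjusted p = 0.0156; adjusted p = 0.28 with an estimated correlation). Of 9 galectins 5 rose, 5 adjusted over the list alone, with Lgals4 at 0.97 (adjusted p = 0.0279; adjusted p = 0.103 with an estimated correlation). Of 25 FOXO targets 14 rose and 7 fell, 14 and 7 adjusted over the list alone, with Trib2 at 3.62 and Txnip at 3.08 (adjusted p = 0.0233; adjusted p = 0.257 with an estimated correlation). Macrophage genes rose in 16 of 17 cases in these arrays. At the midpoint 17 of 24 prenylation genes fell and 1 rose, 17 and 1 adjusted over the list alone, with Rabggtb, a geranylgeranyl transferase subunit, at -1.66 (adjusted p = 1.38e-04; adjusted p = 0.071 with an estimated correlation), and macrophage genes rose in 15 of 17 cases in those arrays (adjusted p = 9.01e-11; adjusted p = 0.192 with an estimated correlation).

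With lonafarnib, STAT5 targets rose in 6 of 22 cases at the 8093 midpoint, 6 rising and 1 falling adjusted over the list alone, with Pim2 at 1.23 (adjusted p = 0.0073; adjusted p = 0.0893 with an estimated correlation), and glycolysis and hypoxia genes fell in 9 of 24 and rose in 2, 10 and 3 adjusted over the list alone, with Egln3 at -0.96 (adjusted p = 0.00159; adjusted p = 0.385 with an estimated correlation). In these arrays Cpa3 rose by 5.11 and macrophage genes in 6 of 17 cases (adjusted p = 5.03e-06; adjusted p = 0.379 with an estimated correlation). T and NK cell genes fell in 4 of 13 cases at the 8093 end, 5 falling and 1 rising adjusted over the list alone, with Thy1 at -2.22 (adjusted p = 0.00733; adjusted p = 0.122 with an estimated correlation), where Cpa3 rose by 4.37. At the Bin-2 end their median was 0.03 and their mean -0.27, with 3 of 13 falling, 4 adjusted over the list alone, and the test downwards (adjusted p = 0.0229; adjusted p = 0.197 with an estimated correlation). That call was lost without end replicate 2 (adjusted p = 0.0685). The interferon list went up at the nilotinib midpoint of Bin-2 with 1 of 28 genes rising, 6 adjusted over the list alone (adjusted p = 0.0186; adjusted p = 0.391 with an estimated correlation), and was not called without start replicate 1 (adjusted p = 0.133). In these arrays 14 of 17 macrophage genes rose, with list means of 6.21 and 8.35. The BCL2 family (5 of 14 up, 5 down, 6 and 5 adjusted over the list alone; adjusted p = 0.896) and the stress response list (9 of 25 up, 8 down, 10 and 8 adjusted over the list alone; adjusted p = 0.838) were not called at the nilotinib midpoint of 8093.

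Xist group means lay between 10.8 and 11.7 in all 12 groups, and Uty (2.51 to 2.97), Eif2s3y (2.05 to 2.41) and Kdm5d (2.77 to 3.32) were low in all 12. Gata2, a transcription factor of mast cells, ran from 4.57 to 11.27 between group means.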
